A study of Mus musculus with 4 samples.

How the data were processed

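Bulk RNA sequencing measured gene expression in cDC1 sorted from lung tumours of mice (KP per the protocol, WT per the genotype label) after PBS, PD-1Ab, PD-1Ab7, or Flt3L with PD-1Ab7, with 1 library per treatment. Per the labels, total RNA was extracted with TRIzol and stranded mRNA libraries were made with a KC-Digital kit; whether duplicate reads were collapsed is not stated. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.3a, featureCounts and the builds GRCh38 and GRCm38, without order or further settings, and the genes are those of mouse. The deposited table holds 1 RPKM value per gene and library, computed by the authors, with 39083 rows and no read counts. Gene places and lengths came from GENCODE vM21 on GRCm38. Whether featureCounts counted by strand is not stated, so reads in exons that overlap another gene are uncertain, and the report names these genes.

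RPKM times exon length fell on multiples of 1 step per library. The step gave the read total implied by the scaling: 17059343 in the PBS library, 25360562 in PD-1Ab, 18568725 in PD-1Ab7 and 23643601 in the combination. Whether the authors' total held all mapped reads or only those assigned to genes was not checked. With these totals, 89.0% to 89.9% of the values below 100 reads came within 0.02 of a whole read, and 63.7% to 66.8% were even, so neither reads nor pairs as the unit counted is settled. Counts were taken as read pairs, the coarser unit, which widens the intervals and lowers the bounds against 0 if single reads were counted. The counts served only for exact (Clopper-Pearson) 95% intervals of the ratio between 2 libraries and for the redrawing of reads; the gene models are close to those of the authors but not identical. Where a library held 0 reads, the fold is a lower bound against a floor of 3 read pairs per library.

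Rows whose gene names a spreadsheet had turned into dates were left out, 26 in all, of which 18 had a mean of at least 1 RPKM, and 39057 genes were kept, of which 14792 were 0 in all libraries. Differences were taken between log2(RPKM + 1) of single libraries, on the authors' scaling. A gene counted as apart at a difference of at least 1 in size among the 12172 genes with a mean of at least 1 RPKM. The 5 comparisons were PD-1Ab with PBS, PD-1Ab7 with PBS, PD-1Ab7 with PD-1Ab, the combination with PD-1Ab7 and the combination with PBS. No test was run and no p-value is given, since a test needs replicates. For 41 gene lists (DC subsets and maturation, antigen presentation, costimulatory and inhibitory molecules, chemokines, cytokines, interferon and NF-kB responses, pattern receptors, cell cycle, metabolism, stress, organelle and ribosomal genes, and markers of other cell types), the median difference was set against 10000 random lists of the same size, matched in 20 bins of expression, when at least 5 members passed the filter. A list was called below the 2.5 or above the 97.5 percentile.

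Genes were named by a rule: in each comparison the 10 largest differences in each direction among genes with a mean of at least 5 RPKM, leaving out predicted genes, receptor segments and mitochondrial genes; up to 4 members of each list with the largest difference and its most abundant member; and 26 genes fixed by name. Where microRNA and other small RNA genes took places among the 10, further genes were added after the values were seen, and the text says so. The rule on size was tested on simulated data: it recovered 62% to 72% of differences of 2.5-fold and 83% to 89% of 4-fold, and 146 to 171 unchanged genes passed it. The list rule called 6.67% of lists with no shift and 100% of lists of 18 members shifted by 0.5. The lists were drawn at random from the simulated genes, and the simulation held counting noise alone. The check therefore gives no rate of false calls for lists whose members are expressed together. Alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 RPKM, 3 other scalings, protein-coding models alone, and leaving out markers of other cell types. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.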

Results

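Type 1 conventional dendritic cells (cDC1), the dendritic cell (DC) subset that takes up dead tumour cells and presents their antigens to CD8 T cells, were sorted from lung tumours of KP mice, in which inhaled adenoviral Cre switches on mutant Kras and removes Tp53 in the lung. Messenger RNA was sequenced in bulk. The protocol and the title line of the table name KP mice, whereas the sample labels give the genotype as WT, and the title line calls the cells cDC1 T cells where the labels say sorted cDC1; both points are left as given. Mice had received intraperitoneal PBS, PD-1Ab, PD-1Ab7, or Flt3L together with PD-1Ab7, and each treatment is represented by 1 library, 4 in all. Flt3L is the growth factor that drives the formation of cDC1. The labels do not spell out PD-1Ab7, and the name is used as given; the series title names CCL7 and Flt3L as the targets combined with anti-PD-1 therapy. The library from mice given Flt3L and PD-1Ab7 is called the combination library. The deposited values are RPKM, read counts scaled to gene length and to the total of the library, and 12172 genes had a mean of at least 1 RPKM over the 4 libraries. The step size of the values implied a total of 17059343 reads in the PBS library, 25360562 in the PD-1Ab library, 18568725 in the PD-1Ab7 library and 23643601 in the combination library. There was no replicate check, since each group holds 1 library, so every difference is between single libraries and carries no p-value. Intervals of folds and ratios are exact 95% intervals of a ratio of read-pair counts and cover counting error only, as PCR reads are not independent molecules. Folds are ratios of RPKM; a gene counted as 2-fold apart when its log2(RPKM + 1) differed by at least 1, and a list median is the median of its members' log2 differences. A list called higher or lower had a median outside the central 95% of 10000 random lists matched on expression, which understate the chance spread because list members are expressed together.

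All 4 libraries held the transcripts that define cDC1. Xcr1, the receptor for the chemokine XCL1 (chromosome 9, 123852315 to 123862029 of GRCm38, minus strand), stood at 29.4 RPKM in the PBS library, 43.3 in PD-1Ab, 26.3 in PD-1Ab7 and 20.7 in the combination. Clec9a, the receptor for dead-cell actin (chromosome 6, 129408862 to 129424763, plus strand), stood at 78.4, 116, 66.9 and 53.9 RPKM in the same order; its exons overlap those of Clec1b on the same strand, so its counts carry that uncertainty. The transcription factors Irf8 and Batf3, both needed to form cDC1, stood at 79.4 to 112 and 30.5 to 39.4 RPKM, and the MHC class II gene H2-Ab1 at 8760 to 13325 RPKM. Flt3, the receptor for Flt3L (chromosome 5, 147330741 to 147400489, minus strand), stood at 46.1, 53.3, 46.4 and 33.5 RPKM. Transcripts of other cells were present as well: the median of 15 alveolar macrophage markers was 71.2 RPKM in the PBS library, 11.6 in PD-1Ab, 49.4 in PD-1Ab7 and 66.0 in the combination. The median of 18 T cell markers was 4.96, 4.28, 7.33 and 12.7 RPKM. The sums of RPKM ran from 421171 in the PBS library to 445286 in the PD-1Ab7 library.

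The first comparison, PD-1Ab against PBS, asks how anti-PD-1 treatment alone changed the sorted cells. Macrophage and neutrophil transcripts were lower in the PD-1Ab library, whereas cDC1, MHC class II, ribosomal and endothelial transcripts were higher. Of 15 alveolar macrophage markers, 14 were at least 2-fold lower (list median -2.07), and the exception, Plet1, is also a member of the cDC1 list. Chil3, which encodes the chitinase-like protein Ym1 of lung macrophages (chromosome 3, 106147554 to 106167564, minus strand), stood at 141 RPKM against 861, 6.12-fold lower (5.88 to 6.38); it has near-identical relatives, so its reads may be shared. Arginase 1 (Arg1, chromosome 10, 24915221 to 24927484, minus strand), which depletes arginine in tumour macrophages, stood at 1.18 against 20.9 RPKM, 17.8-fold lower (12.5 to 26.3). Among the single genes with the largest differences, Ctsk, the protease cathepsin K, was 6.62-fold lower, Ctsd, cathepsin D, was 5.27-fold lower with exons shared with Gm49369, Gpnmb was 9.77-fold lower, the proton pump subunit gene Atp6v0d2 5.82-fold and the ion channel gene Mcoln3 6.76-fold. The scavenger receptor genes Mrc1 (the mannose receptor) and Olr1 (the receptor for oxidised lipoprotein) were 6.24-fold and 6.80-fold lower, and Lpl, lipoprotein lipase, was 5.79-fold lower. Among the named genes, the largest fold lower was that of Ighg3, the constant region of immunoglobulin G3 (chromosome 12, 113356224 to 113361232, minus strand), at 0.583 against 34.5 RPKM, 59.2-fold lower (36.8 to 96.6), with some reads open to sharing among the constant regions.

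The same direction was seen in further myeloid lists. Interstitial macrophage markers had a median of -0.87, with Mertk, a receptor for dying cells, 4.90-fold lower and Adgre1, which encodes F4/80, 3.97-fold lower. Neutrophil markers had a median of -1.37, with 9 of 13 at least 2-fold lower: the collagenase gene Mmp8 6.84-fold, Csf3r, the G-CSF receptor gene, 4.48-fold, and S100a9, a calprotectin subunit, at 73.2 against 244 RPKM, 3.33-fold. The monocyte list stayed within the random range (-0.16). cDC2 markers were lower (-0.48), Sirpa by 4.70-fold. Plasmacytoid DC markers had a median of -0.60 with 3 of 5 members lower, none by 2-fold on the log2(RPKM + 1) scale. That median shrank to -0.10 without the filter on low values. B cell markers had a median of -0.68, with Cd22 4.16-fold and Cd19 3.17-fold lower. Lung epithelial markers went both ways, with 10 of 16 lower, 6 higher and a median of -0.93: the keratin genes Krt18 and Krt19 were 4.04-fold and 3.73-fold lower and Sftpc, surfactant protein C, 2.08-fold at 184 against 382 RPKM, while the club-cell secretoglobin Scgb1a1 went the other way, 3.07-fold higher at 125 against 40.6. T cell markers had a median of -0.28. DC cytokine genes had a median of -0.34 (11 of 16 lower), among them Osm, oncostatin M, 4.80-fold lower, the interleukin 1 receptor antagonist gene Il1rn 4.67-fold, Il1a 2.94-fold and Il23a 2.74-fold. Macrophage and neutrophil lists moved the same way, so RNA of other cells may contribute. Inhibitory molecules (-0.27), chemokine receptors (-0.32, 8 of 13 lower) and NF-kB targets (-0.23, 15 of 22 lower) were also lower, with Tigit 2.54-fold and Ccr1, a receptor for CCL7, 3.79-fold lower at 2.42 against 9.19 RPKM. Mature migratory DC genes were lower for 16 of 18 members (-0.28), including the actin bundler Fscn1, 1.35-fold. Mitochondrially encoded transcripts had a median of -0.32 (9 of 13 lower); the genes overlap each other and have nuclear copies, and mt-Co3 at 0.598 to 2.72 RPKM beside mt-Nd4l at 1957 to 3253 RPKM shows that the counts of single genes are uncertain.

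Higher in the PD-1Ab library were 18 of 19 cDC1 identity genes (median 0.56), with the cDC1 genes Gcsam 1.73-fold, Naaa, a lysosomal amidase gene, 1.66-fold and Ifi205, an interferon-inducible gene, 1.81-fold higher at 524 against 290 RPKM. MHC class II presentation had a median of 0.52, with the invariant chain gene Cd74 at 5231 against 3306 RPKM, 1.58-fold, and H2-Ab1 1.52-fold. Macrophage, neutrophil and B cell lists were lower in this library. A higher share of cDC1 RNA may therefore contribute to both rises, which was not tested. Interferon gamma response genes had a median of 0.22 (18 of 26 higher): Cxcl9, the CXCR3 ligand that recruits T cells (chromosome 5, 92321347 to 92328079, minus strand), stood at 62.4 against 24.4 RPKM, 2.55-fold higher (2.34 to 2.79), and the GTPase gene Iigp1 was 2.40-fold higher. The GTPase genes Tgtp1 and Tgtp2, near-identical copies, were 2.44-fold and 2.41-fold higher, with an uncertain split between them. Ccl4, a CCR5 ligand gene (chromosome 11, 83662584 to 83664683, plus strand), was 3.03-fold higher (2.35 to 3.95). The chemokine list as a whole had a median of 0.01, since Cxcl2 (4.24-fold), Cxcl1 (3.29-fold) and Ccl6 (3.67-fold) were lower. Endothelial markers were higher for 12 of 12 members (0.95), with Tek, the angiopoietin receptor gene, 2.72-fold, Cldn5, a tight-junction gene, 3.20-fold and Egfl7, whose exons hold a microRNA, 3.15-fold higher. Tmem100, an endothelial membrane gene, was 4.81-fold higher (3.57 to 6.78) and Inmt, a methyltransferase gene of lung stroma, 3.97-fold (3.09 to 5.17). The fibroblast list had a median of 0.57, with Mgp 2.31-fold higher. Ribosomal protein genes were higher for 34 of 34 (0.41), Rps27 by 1.89-fold, nuclear respiratory chain genes had a median of 0.37 with Cox5a 2.00-fold higher, plasma cell markers 0.35 (6 of 11 higher) and G1/S genes 0.17 (15 of 25 higher). Chosen after their values were seen were Scgb1a1, Ccl4, Cldn5 and Cxcl9, and also Ly6a (3.10-fold higher), Gpx3, an antioxidant enzyme gene (3.42-fold), and Hpgd, which breaks down prostaglandins (2.68-fold). The calls of T cell, plasmacytoid DC, chemokine receptor and plasma cell lists ended under at least 1 alternative, that of T cell markers in 4 of 8. In all, 300 genes were at least 2-fold higher and 536 lower, a share of 35.9% higher; among protein-coding genes the split was 70 to 303, or 18.8%, and without mitochondrial, ribosomal, haemoglobin and receptor segment genes 181 to 537, or 25.2%.

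**Figure D1:**
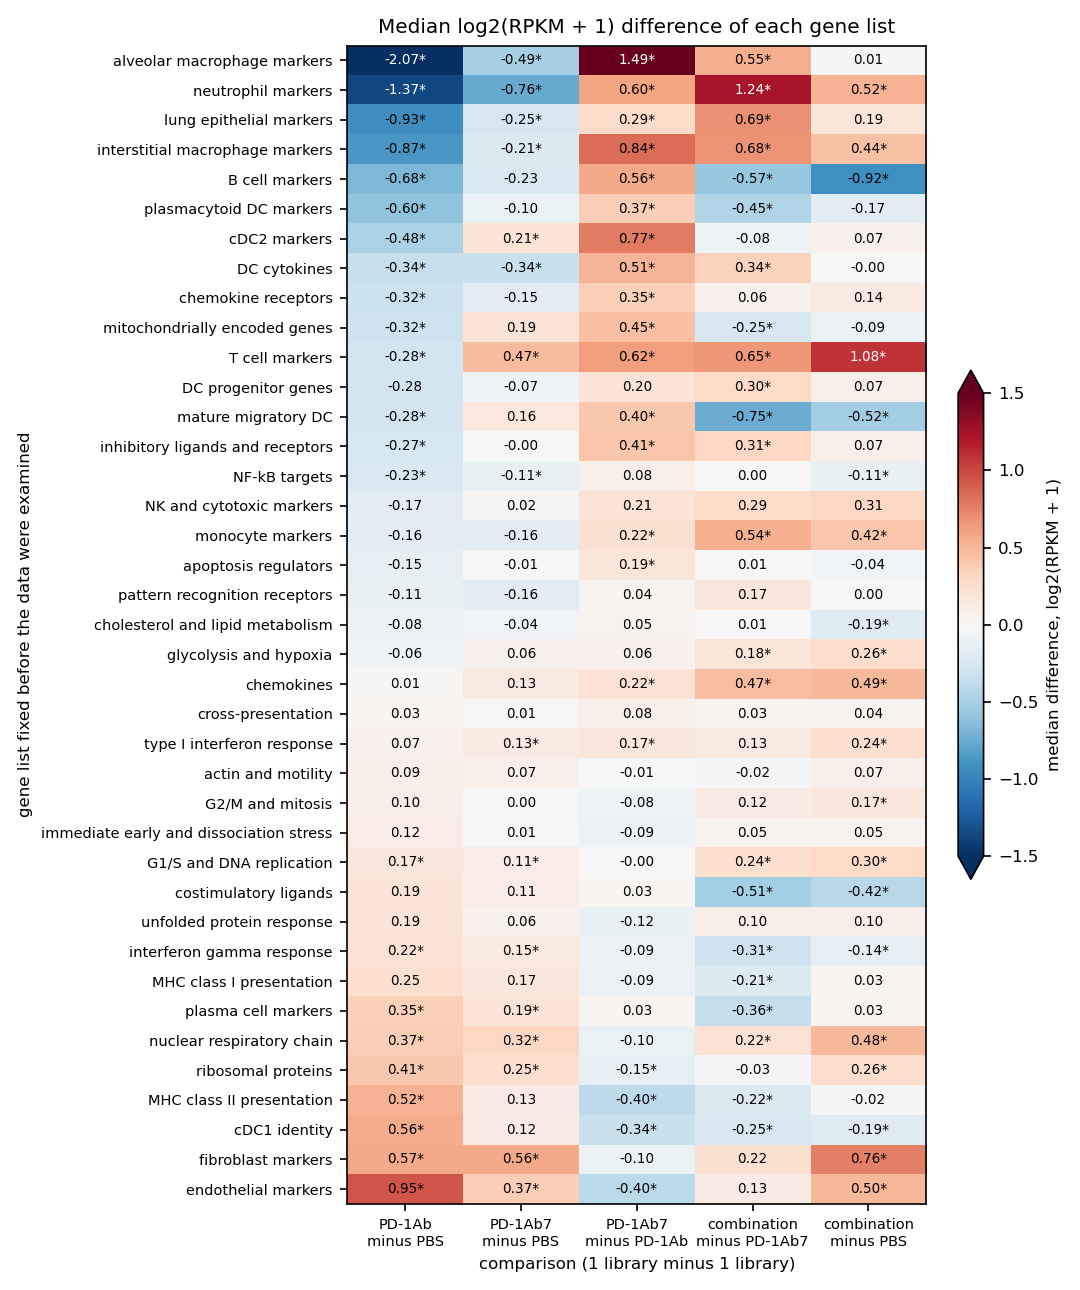
Median difference of log2(RPKM + 1) of each gene list (rows) in each of the 5 comparisons of single libraries (columns), with color from blue (lower) to red (higher). Alveolar macrophage markers stand at -2.07 in PD-1Ab minus PBS and at 1.49 in PD-1Ab7 minus PD-1Ab, and mature migratory DC genes at -0.75 in the combination minus PD-1Ab7.

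PD-1Ab7 against PBS asks what PD-1Ab7 changed, and this pair differed in fewer genes, 242 higher and 270 lower, of which 46 and 54 were protein-coding. T cell transcripts were higher and neutrophil and macrophage transcripts lower in the PD-1Ab7 library, and the cDC1 identity list stayed within the random range (0.12). The mast cell protease genes Mcpt2 and Mcpt1 (chromosome 14, 56042041 to 56044642 and 56017971 to 56020384, plus strand), near-identical copies, stood at 26.6 and 22.2 RPKM against 0, at least 80.3-fold and at least 64.0-fold higher against a floor of 3 read pairs per library; the split between the copies is uncertain. T cell markers had a median of 0.47, with the receptor constant region Trac 2.08-fold, the signalling adaptor gene Lat 1.97-fold and Cd3g, a chain of the T cell receptor complex (chromosome 9, 44969572 to 44980431, minus strand), 1.82-fold higher. Tcrg-C2, a constant region of the gamma chain, was 5.91-fold higher (2.64 to 15.5) at 5.30 against 0.898 RPKM. Pdcd1, the gene for PD-1 itself (chromosome 1, 94038305 to 94052553, minus strand), was 1.70-fold higher at 8.48 against 4.98. cDC2 markers had a median of 0.21 but went both ways, with 6 of 11 higher and 5 lower; the lectin gene Mgl2 was 2.12-fold higher at 46.5 against 21.9 RPKM, whereas Sirpa had a log2 difference of -0.76 and Clec4a2 of -0.70. Ccl17, a CCR4 ligand gene of mature DCs, stood at 755 against 418, 1.81-fold higher. Il27 was 4.78-fold higher with a wide interval (1.80 to 15.9). Interferon gamma response genes (0.15, 17 of 26 higher; Cxcl9 1.68-fold), type I interferon genes (0.13, 18 of 26), ribosomal protein genes (0.25; 34 of 34 higher), nuclear respiratory chain genes (0.32), G1/S genes (0.11, 16 of 25), plasma cell (0.19, 7 of 11), endothelial (0.37) and fibroblast markers (0.56; Mgp 2.13-fold) were higher too. Igfbp6, a growth factor binding protein gene, was 4.26-fold higher (2.91 to 6.41). Of the genes chosen after their values were seen, Tnfrsf4, which encodes the costimulatory receptor OX40, was 2.25-fold higher at 23.3 against 10.3 RPKM, Penk, proenkephalin, 2.52-fold, Tmem100 2.66-fold, Gpx3 2.67-fold, Csrp2 2.35-fold and Scgb1a1 2.53-fold.

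Lower in PD-1Ab7 than in PBS were neutrophil markers (-0.76), alveolar macrophage markers (-0.49), interstitial macrophage markers (-0.21, 9 of 15 lower), DC cytokines (-0.34), NF-kB targets (-0.11, 14 of 22) and lung epithelial markers (-0.25, 10 of 16). Ighg3 was 49.5-fold lower, with reads open to sharing among constant regions. Lpl was 2.17-fold and Mrc1 1.74-fold lower, and the monocyte receptor gene Cd300e 5.80-fold. The cytokine genes Tnf and Il1a were 1.75-fold and 1.72-fold lower and the neutrophil-attracting Cxcl2 1.77-fold. RNA of other cells may contribute to the lower cytokine values, since macrophage and neutrophil lists were lower too. Mki67, a proliferation marker, stood at 88.7 against 113 RPKM, 1.27-fold lower, while the G2/M list stayed within the random range. Chosen after their values were seen were S100a9, 2.26-fold lower at 108 against 244 RPKM, S100a8, 2.60-fold lower, Csf3r, 2.75-fold lower, and Acod1, which makes itaconate in activated macrophages, 2.64-fold lower at 8.77 against 23.1 RPKM. The calls of cDC2, G1/S, interstitial macrophage, lung epithelial and plasma cell lists each ended under at least 1 alternative. The galanin gene Gal was 2.84-fold lower, the chitinase-like gene Chil1 2.51-fold and the iron-sulfur assembly gene Isca2 2.95-fold, chosen in the same way.

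PD-1Ab7 against PD-1Ab asks what PD-1Ab7 changed beyond PD-1Ab. Macrophage, cDC2 and neutrophil transcripts were higher in the PD-1Ab7 library. The comparison shares the PD-1Ab library with the first, so a low value in that library alone would give opposite signs in both, and the 2 are not independent. Alveolar macrophage markers had a median of 1.49, with 14 of 15 at least 2-fold higher: Chil3 stood at 771 against 141 RPKM, 5.48-fold higher (5.26 to 5.71), and Fabp1 was 3.76-fold higher. Arg1 was 13.7-fold higher (9.65 to 20.4) at 16.1 against 1.18 RPKM, Mmp12, macrophage elastase, 6.62-fold, Gpnmb 5.94-fold, Ctsk 4.27-fold, Atp6v0d2 4.11-fold, and the chemokine gene Ccl6 stood at 771 against 193 RPKM (interval of the ratio 3.87 to 4.14). Interstitial macrophage markers had a median of 0.84, with the lipid sensor gene Trem2 11.4-fold and the complement gene C1qa 3.15-fold higher. Clec4n, the fungal pattern receptor Dectin-2, was 5.36-fold higher. cDC2 markers had a median of 0.77 (Sirpa 2.70-fold, Mgl2 2.48-fold), neutrophil markers 0.60 (Mmp8 3.82-fold), plasmacytoid DC markers 0.37, monocyte markers 0.22 (8 of 12 higher), B cell markers 0.56 (Cd19 2.60-fold, Blk 2.91-fold) and lung epithelial markers 0.29 (10 of 16 higher; Cdh1 3.26-fold, Krt18 2.43-fold). T cell markers had a median of 0.62, with Cd8b1 2.52-fold and Cd3g 2.32-fold higher, and the granzyme gene Gzmb was 2.91-fold higher. Mcpt2 had a ratio of 164 (49.0 to 1485) and Mcpt1 of 96.5 (32.1 to 465), and both rest on few read pairs in the PD-1Ab library.

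DC maturation genes were higher as well. All 18 mature migratory DC genes were higher in PD-1Ab7 than in PD-1Ab (0.40), among them Ccr7, the receptor that guides DCs to lymph nodes (chromosome 11, 99144196 to 99155077, minus strand), at 124 against 81.0 RPKM, 1.54-fold, Fscn1 at 85.0 against 46.0, 1.85-fold, and the calcium channel subunit gene Cacnb3, 1.66-fold. Inhibitory molecules had a median of 0.41, with Ctla4 at 54.8 against 22.5 RPKM, 2.43-fold higher, and Tigit 2.60-fold, both also genes of T cells. DC cytokines had a median of 0.51, with 11 of 16 higher (Osm 3.06-fold, Il1rn 2.99-fold) and 5 lower, Il12b among them. Like the macrophage lists, Osm and Il1rn were lower in PD-1Ab than in PBS, so RNA of other cells may contribute. Chemokine receptors had a median of 0.35 (9 of 13 higher), type I interferon genes 0.17 (18 of 26), apoptosis regulators 0.19 and mitochondrially encoded transcripts 0.45. The chemokine list had a median of 0.22 with 9 of 17 higher, Ccl9 3.42-fold and Cxcl2 2.39-fold; its sign changed to -0.049 without a filter on low values and to -0.042 without markers of other cell types. The plasmacytoid DC call, on 5 members, held in 3 of 7 alternatives and the monocyte call in 6 of 8, and those of chemokine receptors, type I interferon genes and apoptosis regulators also ended under at least 1. Cd70, a ligand gene for T cell costimulation, was 7.74-fold higher. Lower in PD-1Ab7 than in PD-1Ab were the cDC1 identity (-0.34), MHC class II (-0.40, 9 of 13 lower), ribosomal (-0.15) and endothelial lists (-0.40): Clec9a was 1.74-fold, Xcr1 1.65-fold, H2-Ob 1.55-fold and Pecam1 1.86-fold lower. Ccl4 was 2.74-fold lower (2.16 to 3.50), Cxcl9 1.52-fold, Iigp1 1.86-fold and Il12b 1.16-fold. Of the genes chosen after their values were seen, Tlr3, the receptor for double-stranded RNA in cDC1, stood at 8.56 against 17.9 RPKM, 2.09-fold lower, and Ccl3, Cd226 and Ccl2 were 2.05-fold, 2.08-fold and 2.18-fold lower. The split was 322 higher to 202 lower; among protein-coding genes it was 158 to 17, or 90.3% higher, and at a mean of at least 5 RPKM 174 to 66, or 72.5%.

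The combination against PD-1Ab7 asks what Flt3L added. It shares the PD-1Ab7 library with both preceding comparisons and is not independent of them. A high value in that library alone would make a gene higher there and lower here. DC maturation and costimulatory genes were lower in the combination library, and neutrophil, macrophage, T cell and epithelial transcripts were higher. All 18 mature migratory DC genes were lower (-0.75), 5 of them at least 2-fold: Ccr7 stood at 60.1 against 124 RPKM, 2.07-fold lower (1.94 to 2.22), Ccl22 at 81.2 against 173, 2.13-fold (2.02 to 2.24), Fscn1 at 42.0 against 85.0, 2.02-fold, and Ccl17 at 451 against 755, 1.67-fold. Il12b, the p40 subunit of interleukin 12 that drives T cell interferon production (chromosome 11, 44400063 to 44414033, plus strand), stood at 352 against 695 RPKM, 1.98-fold lower (1.92 to 2.03). Costimulatory molecules had a median of -0.51, with Cd40, the receptor for T cell help, at 18.1 against 36.7 RPKM, 2.03-fold lower, Cd70 4.12-fold, Icosl 1.66-fold, Cd83 1.55-fold and Cd86 1.45-fold. Cd274, which encodes PD-L1 (chromosome 19, 29367455 to 29388095, plus strand), stood at 58.9 against 78.9 RPKM, 1.34-fold lower, and a gene on the opposite strand overlaps its exons. cDC1 identity genes had a median of -0.25, with Flt3 1.38-fold, Xcr1 1.27-fold, Clec9a 1.24-fold, Irf8 1.23-fold, Batf3 1.25-fold and the DC transcription factor Zbtb46 1.52-fold lower. MHC class I (-0.21) and class II (-0.22), interferon gamma response (-0.31; Cxcl9 1.81-fold, Serpina3g 1.73-fold), plasmacytoid DC (-0.45), B cell (-0.57), plasma cell (-0.36) and mitochondrially encoded (-0.25) lists were lower, and the NF-kB subunit gene Relb was 1.61-fold lower. The MHC class I and class II medians fell no further than that of cDC1 identity genes (-0.25). Dilution of cDC1 RNA by RNA of other cells may contribute and was not tested for the MHC lists. Tgtp1 was 2.24-fold lower, with the uncertain split from Tgtp2. Ccl5, a T cell attracting chemokine gene, was 3.68-fold lower (2.99 to 4.57) at 10.7 against 39.3 RPKM, and Il27 4.73-fold. Ighg1 (chromosome 12, 113325240 to 113330523, minus strand) was 16.1-fold lower (10.3 to 26.5) and Mcpt2 7.45-fold, both with possible read sharing among copies. Apol7c, an apolipoprotein gene of mature cDC1 (chromosome 15, 77524852 to 77533316, minus strand), was 2.29-fold lower at 85.5 against 195 RPKM, Serpinb6b, a granzyme inhibitor gene, 2.25-fold, Nudt17 2.41-fold, and H2-M2, a class I-like gene with many relatives, 2.25-fold; these 4 were chosen after their values were seen.

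Higher in the combination than in PD-1Ab7 were neutrophil markers (1.24, 8 of 13 at least 2-fold), with S100a9 at 711 against 108 RPKM, 6.59-fold (6.01 to 7.23), S100a8 7.03-fold (5.33 to 9.45), Csf3r 3.82-fold and Trem1 3.02-fold. Slfn4, a Schlafen gene of myeloid cells (chromosome 11, 83175186 to 83190216, plus strand), stood at 68.3 against 6.40 RPKM, 10.7-fold higher (9.33 to 12.2). Cxcl13, the B cell attracting chemokine gene (chromosome 5, 95956951 to 95961068, plus strand), was 9.90-fold higher (6.13 to 17.0), Acod1 5.26-fold at 46.1 against 8.77 RPKM, Arg1 4.54-fold at 73.2 against 16.1, and G0s2, an inhibitor of fat breakdown, 3.64-fold. Macrophage lists were higher, alveolar with a median of 0.55 (Chil3 1.79-fold, Ctsk 1.88-fold), interstitial 0.68 (Apoe 1.60-fold) and monocyte 0.54 (F13a1 2.40-fold). T cell markers had a median of 0.65, with Trbc1 2.90-fold, Thy1 2.49-fold at 36.0 against 14.5 RPKM, Cd3e 2.20-fold and Cd3g 2.06-fold higher. Inhibitory molecules went both ways, with 8 of 14 higher, 6 lower, Cd274 among them, and a median of 0.31: Ctla4 stood at 99.9 against 54.8 RPKM, 1.82-fold higher, and Pdcd1 at 15.2 against 8.48, 1.79-fold (1.48 to 2.18), both also T cell genes. Chemokines had a median of 0.47 (12 of 17 higher), with Cxcl2 at 217 against 85.1 RPKM, 2.55-fold, Ccl24, an eosinophil attractant gene, 34.2-fold (9.18 to 287), and Ccl7 (chromosome 11, 82045712 to 82047525, plus strand) at 6.81 against 2.08 RPKM, 3.27-fold (1.82 to 5.91). DC cytokines had a median of 0.34, with 11 of 16 higher, Il10 by 3.43-fold and Il18 by 1.90-fold, and 5 lower, Il12b and Il27 among them. With macrophage and neutrophil lists higher too, RNA of other cells may contribute to the higher members. DC progenitor genes had a median of 0.30 (4 of 6 higher), a call that held in 6 of 8 alternatives. Lung epithelial markers had a median of 0.69, with Krt8 3.53-fold, Krt18 3.46-fold, Sftpb 2.88-fold and Scgb1a1 2.17-fold higher, and outside the list Scgb3a1, an airway secretoglobin gene, was 5.84-fold higher. G1/S genes (0.24), glycolysis (0.18; the lactate exporter gene Slc16a3 2.90-fold) and nuclear respiratory chain genes (0.22) were higher. The split was 340 higher to 163 lower, and 121 to 28, or 81.2% higher, among protein-coding genes.

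**Figure D2:**
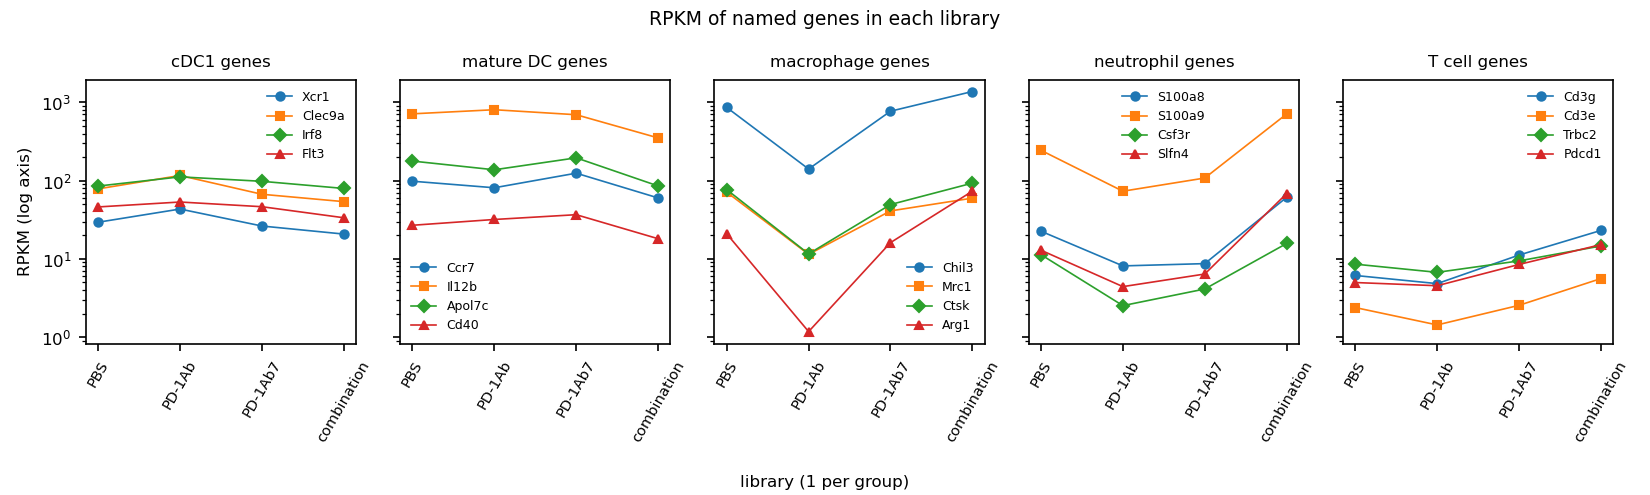
RPKM (log axis) of genes of interest in the 4 single libraries, 1 mark per library. Ccr7 stands at 98.2, 81.0, 124 and 60.1 RPKM and Il12b at 714, 805, 695 and 352 RPKM in the PBS, PD-1Ab, PD-1Ab7 and combination libraries.

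The combination against PBS asks how the full treatment differed from none. T cell markers had the highest list median (1.08): all 18 markers were higher in the combination library, 12 of them at least 2-fold. Cd3g stood at 23.1 against 6.13 RPKM, 3.76-fold higher (3.19 to 4.46), Trac was 3.45-fold, Thy1 3.24-fold and Cd3d 3.09-fold higher. Tcrg-C2 (chromosome 13, 19304649 to 19307551, minus strand) was 14.6-fold higher (6.92 to 37.1), the tissue-homing receptor gene Cxcr6 7.04-fold (4.27 to 12.4) and Gzmb 3.40-fold. Pdcd1 stood at 15.2 against 4.98 RPKM, 3.05-fold higher (2.39 to 3.93), and Ctla4 at 99.9 against 38.0, 2.63-fold. Myeloid transcripts were higher, with medians of 0.52 for neutrophil (S100a9 2.92-fold, S100a8 2.71-fold), 0.44 for interstitial macrophage (C1qb 2.44-fold, Cd14 2.02-fold) and 0.42 for monocyte markers (8 of 12 higher; Ace 2.26-fold), whereas alveolar macrophage markers stayed within the random range (0.01). Slfn4 was 5.30-fold, Cxcl13 6.82-fold, the protease inhibitor gene Wfdc17 4.38-fold and Penk 4.45-fold higher. Scgb1a1 stood at 223 against 40.6 RPKM, 5.50-fold higher. Chemokines had a median of 0.49, with Ccl9 1.99-fold, Ccl6 1.58-fold and Ccl7 1.86-fold (1.17 to 3.11) higher, and Ccl24 at 5.68 against 0 RPKM, at least 20.9-fold. Type I interferon genes had a median of 0.24 (18 of 26 higher), with Isg15 1.90-fold, Ifit3 1.93-fold, Oasl2 2.19-fold and Zbp1 2.15-fold higher. Growth genes were higher: G1/S 0.30 (the replication helicase genes Mcm7 1.73-fold and Mcm5 1.63-fold), G2/M 0.17 (17 of 26 higher; Birc5 1.71-fold), glycolysis 0.26, nuclear respiratory chain 0.48 and ribosomal protein 0.26. Endothelial markers had a median of 0.50 (Tmem100 3.10-fold, Egfl7 2.45-fold) and fibroblast markers 0.76 (Dcn 2.28-fold, Mgp 1.87-fold). Mcpt2 stood at 3.57 against 0 RPKM, at least 10.8-fold higher, and Mcpt1 at least 7.12-fold, chosen after its values were seen, as were Arg1 (3.50-fold) and Cd3g.

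Lower in the combination than in PBS were B cell markers (-0.92; Cd79a 4.28-fold, Fcmr 2.71-fold), mature migratory DC genes (-0.52; Ccr7 1.64-fold, Ccl22 1.75-fold), costimulatory molecules (-0.42; Cd40 1.49-fold, Cd86 1.41-fold), cDC1 identity genes (-0.19), interferon gamma response genes (-0.14, 17 of 26 lower), NF-kB targets (-0.11, 15 of 22) and cholesterol and lipid metabolism genes (-0.19, 15 of 21). The calls of chemokines, type I interferon, G2/M and NF-kB lists in this comparison each ended under at least 1 alternative. Among cDC1 genes, Xcr1 was 1.42-fold, Clec9a 1.46-fold and Flt3 1.38-fold lower. Il15, which sustains CD8 T cells, stood at 2.77 against 5.68 RPKM, 2.05-fold lower. Ighg3 and Ighg1 were 40.1-fold and 17.4-fold lower, Ighd 2.75-fold and Iglc1 3.19-fold, with possible read sharing among constant regions, and Mab21l3 was 3.03-fold lower. Of the genes chosen after their values were seen, Il12b stood at 352 against 714 RPKM, 2.03-fold lower (1.97 to 2.09), Apol7c was 2.08-fold, Ccl5 2.25-fold, H2-M2 2.10-fold and As3mt, an arsenic methyltransferase gene, 2.58-fold lower. The split was 370 higher to 183 lower, and 132 to 31, or 81.0% higher, among protein-coding genes.

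Some lists stayed within the random range in all 5 comparisons. In the order PD-1Ab minus PBS, PD-1Ab7 minus PBS, PD-1Ab7 minus PD-1Ab, combination minus PD-1Ab7 and combination minus PBS, the cross-presentation machinery had medians of 0.03, 0.01, 0.08, 0.03 and 0.04, and pattern recognition receptors of -0.11, -0.16, 0.04, 0.17 and 0.00. In the latter list Clec4n, Tlr2 and Clec7a were 5.46-fold, 3.95-fold and 2.49-fold lower in PD-1Ab than in PBS. The unfolded protein response (medians from -0.12 to 0.19), immediate early and dissociation stress genes (-0.09 to 0.12), actin and motility genes (-0.02 to 0.09), and NK and cytotoxic markers (-0.17 to 0.31) also stayed within the range in all 5, with Gzma 3.27-fold higher in the combination than in PD-1Ab7. NK markers lay near the limit in the combination minus PBS (percentile 97.35) and minus PD-1Ab7 (97.22). Pattern receptors did so in the combination minus PD-1Ab7 (97.44). Some alternatives called each of these higher. Of the mast cell and basophil list, 1 member passed the filter, Hdc, the histamine-making enzyme gene, which was 3.19-fold lower in PD-1Ab than in PBS and 2.97-fold higher in the combination than in PD-1Ab7. Of the erythroid and platelet list, 2 members passed, and neither list was set against random lists. The CCL7 receptors Ccr1 and Ccr2 stood at 2.42 to 11.8 and 24.8 to 33.0 RPKM, and Ccr3 stood at 0.155 RPKM or below. Exons of Cd74, Lat, Mcm7 and Tgtp1 overlap another gene on the same strand, and those of Ace, Cd22, Cd3e, Cox5a, F13a1, Il1a, Il27, Krt8, Mmp12, Nudt17, Penk, Plet1 and Tlr3 a gene on the opposite strand, so their values are uncertain to that extent. Flt3l, whose exons overlap another gene on the same strand and whose counts are therefore uncertain, stood at 226 RPKM in the PBS library and at 272 to 273 in the others.

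Along the ladder from PBS through PD-1Ab and PD-1Ab7 to the combination, few genes stepped in 1 direction. Of 1500 genes with a 2-fold range and no tied values, 68 (4.53%) were higher at each step and 33 (2.2%) lower at each step, where 4.17% would fall in each of the 24 orders by chance. With protein-coding models alone these counts were 31 and 10, and with a pseudocount of 5 they were 17 and 14. The most frequent order, with 321 genes (21.4%), ran from PD-1Ab through PD-1Ab7 and PBS to the combination. The PD-1Ab library was lowest in 731 of 1587 genes (46.1%) and the combination library highest in 685 (43.2%). The PD-1Ab step and the Flt3L step, which share no library, overlapped in every pair of directions: 100 genes were lower in PD-1Ab than in PBS and higher in the combination than in PD-1Ab7, against 14.97 if the steps were independent. A further 42 genes went higher and then lower (4.02 if independent), 56 were higher in both steps (8.38) and 22 lower in both (7.18). The values for independent steps ignore that short gene models often pass the rule by counting noise, so they are no baseline for unchanged genes. With protein-coding models alone, 47 genes were lower and then higher, and 7 had the same direction in both steps.

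**Figure D3:**
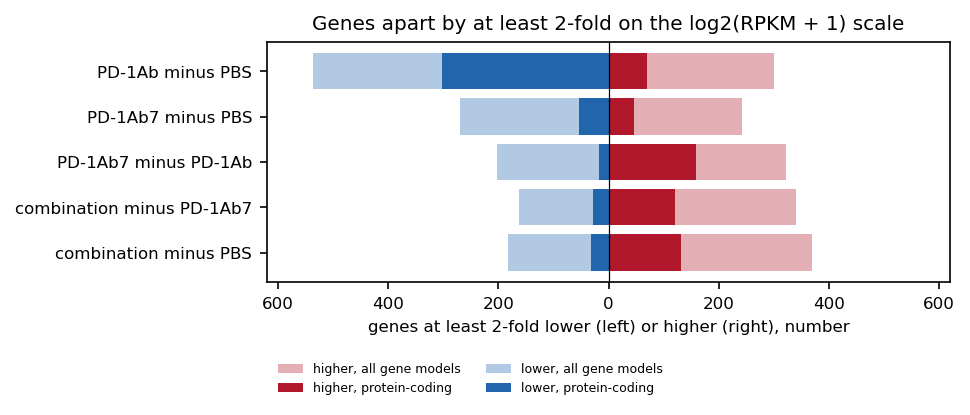
Number of genes at least 2-fold higher (right) or lower (left) in each of the 5 comparisons, over all gene models (light) and protein-coding gene models (dark). PD-1Ab minus PBS has 536 lower and 300 higher genes, of which 303 and 70 are protein-coding.

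Counting noise accounted for part of the counts, and variation between mice, sorts and PCR was not simulated. With reads redrawn at the recovered depths and no true difference, a mean of 158.6 genes passed the 2-fold rule in PD-1Ab minus PBS, where 797 of the same 11807 genes were observed. The observed and redrawn numbers were 493 and 179.8 for PD-1Ab7 minus PBS, 500 and 146.1 for PD-1Ab7 minus PD-1Ab, 487 and 150.7 for the combination minus PD-1Ab7, and 529 and 160.4 for the combination minus PBS. Gene models under 200 nucleotides, mostly microRNA and small nucleolar RNA genes, gave 116 of the 300 higher and 107 of the 536 lower genes in PD-1Ab minus PBS. In PD-1Ab7 minus PBS they gave 117 of 242 and 129 of 270, in PD-1Ab7 minus PD-1Ab 76 of 322 and 111 of 202, in the combination minus PD-1Ab7 116 of 340 and 61 of 163, and in the combination minus PBS 124 of 370 and 81 of 183.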

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

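The gene lists, the comparisons and 7 of the 9 alternatives were set before the data were examined; the restriction to protein-coding models and the removal of markers of other cell types were chosen after the results were seen. No paired analysis was possible because each group holds 1 library. Counts with TMM factors were planned but not run, since the table holds no counts. Of 126 recomputed gene counts, 59 stayed within 1.5 times their value in the report and 67 moved beyond it. Of 9163 recomputed differences of single named genes, 8864 kept their side of the 2-fold rule, 148 newly passed it and 151 no longer passed it. None of those past the rule in the report reversed, and direction was not checked for the rest. Of 1645 recomputed list medians, 1577 kept their call, 30 gained one, 36 lost one and 2 reversed. Rescaling to equal sums of RPKM moved the median of all genes to -0.12 in both comparisons with PBS that hold PD-1Ab or PD-1Ab7 alone. Median-of-ratios scaling and the removal of markers of other cell types left all 14 gene counts within 1.5 times. A pseudocount of 0.1 and the weaker filter admit low values to the 2-fold rule, and a pseudocount of 5 and the stricter filters shrink or remove them; for the other changes the cause was not tested. Depth limits the genes with few reads: in redrawn reads with no true difference, 146.1 to 179.8 genes passed the rule in the 5 comparisons, which came to 64.1% (PD-1Ab minus PBS) to 76.4% (the combination minus PD-1Ab7) of the observed number among gene models under 200 nucleotides, and to 2.7% (PD-1Ab minus PBS) to 8.8% (PD-1Ab7 minus PBS) among longer ones. The redraw leaves out variation between mice, sorts and PCR, so the remainder is not shown to follow treatment.

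With a pseudocount of 0.1, genes higher and lower were 484 and 883 in PD-1Ab minus PBS, 424 and 466 in PD-1Ab7 minus PBS, 621 and 359 in PD-1Ab7 minus PD-1Ab, 568 and 289 in the combination minus PD-1Ab7, and 616 and 341 in the combination minus PBS. Genes rising and falling at each step were 109 and 67, those lower and then higher 220, and those with the same direction in both steps 149. With a pseudocount of 5 the same counts were 87 and 184, 68 and 73, 85 and 62, 102 and 58, 101 and 62, then 17 and 14, 26, and 16. At a mean of at least 5 RPKM they were 127 and 273, 93 and 81, 174 and 66, 123 and 74, 151 and 75, then 24 and 12, 52, and 31. With protein-coding models alone they were 70 and 303, 46 and 54, 158 and 17, 121 and 28, 132 and 31, then 31 and 10, 47, and 7. Without a filter, 372 genes were higher in PD-1Ab7 than in PBS and 287 lower in the combination than in PBS. Rescaled to equal sums, 418 genes were lower in PD-1Ab7 than in PBS, 288 lower in the combination than in PBS, 57 falling at each step and 172 lower and then higher. Without mitochondrial, ribosomal, haemoglobin and receptor segment genes, 181 genes were higher in PD-1Ab than in PBS, 152 in PD-1Ab7 than in PBS and 241 in the combination than in PBS, 108 were lower in the combination than in PD-1Ab7, and 41 had the same direction in both steps.

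List medians that left the called range with a pseudocount of 0.1 were those of plasmacytoid DC (0.38) and type I interferon (0.18) genes in PD-1Ab7 minus PD-1Ab, and of G1/S (0.11) and plasma cell (0.19) genes in PD-1Ab7 minus PBS. With a pseudocount of 5, calls were lost for plasmacytoid DC (0.15), chemokine (0.047) and apoptosis (0.08) lists in PD-1Ab7 minus PD-1Ab, chemokine receptors (-0.15) and T cell markers (-0.15) in PD-1Ab minus PBS, and G2/M genes (0.094) in the combination minus PBS. Calls were gained for G2/M genes in PD-1Ab minus PBS (0.084) and, in the combination minus PBS, for mitochondrially encoded genes (-0.091), NK markers (0.22) and lung epithelial markers (0.17).

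Without a filter, calls were lost for cDC2 markers in PD-1Ab7 minus PBS (0.15), plasmacytoid DC (-0.10) and plasma cell markers (0.10) in PD-1Ab minus PBS, plasmacytoid DC (0.18), type I interferon (0.15) and monocyte lists (0.18) in PD-1Ab7 minus PD-1Ab, and DC progenitor genes in the combination minus PD-1Ab7 (0.13). The chemokine list in PD-1Ab7 minus PD-1Ab reversed to -0.049. Calls were gained for MHC class I genes in PD-1Ab (0.25) and PD-1Ab7 (0.17) against PBS, chemokines (0.13) and pattern receptors (-0.20) in PD-1Ab7 minus PBS, and pattern receptors in the combination minus PD-1Ab7 (0.24).

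At a mean of at least 5 RPKM, calls were lost in PD-1Ab minus PBS for chemokine receptors (-0.28) and T cell markers (-0.30); in PD-1Ab7 minus PBS for G1/S genes (0.082), interstitial macrophage (-0.20) and lung epithelial markers (-0.12); in PD-1Ab7 minus PD-1Ab for chemokine receptors (0.19), type I interferon (0.071), apoptosis (0.18) and monocyte (0.18) lists; in the combination minus PD-1Ab7 for DC progenitor genes (0.26); and in the combination minus PBS for chemokines (0.21), type I interferon (0.13), NF-kB (-0.092) and G2/M (0.19) lists. Calls were gained for DC progenitor (-0.56) and G2/M genes (0.21) in PD-1Ab minus PBS, pattern receptors in PD-1Ab7 minus PBS (-0.22), interferon gamma (-0.13), G2/M (-0.14) and plasma cell lists (-0.21) in PD-1Ab7 minus PD-1Ab, apoptosis regulators in the combination minus PD-1Ab7 (-0.15), and mitochondrially encoded (-0.18) and lung epithelial (0.21) lists in the combination minus PBS.

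NK markers in the combination minus PBS gained a call with median-of-ratios scaling (0.29), rescaling to equal sums (0.28), removal of mitochondrial, ribosomal, haemoglobin and receptor segment genes (0.26) and protein-coding models alone (0.31), and with the last also in the combination minus PD-1Ab7 (0.29). Rescaling to equal sums ended the calls of plasmacytoid DC markers in PD-1Ab7 minus PD-1Ab (0.36) and of G1/S genes in PD-1Ab7 minus PBS (0.033). Removal of mitochondrial, ribosomal, haemoglobin and receptor segment genes brought in mature migratory DC genes in PD-1Ab7 minus PBS (0.094), MHC class I genes in PD-1Ab (0.17) and PD-1Ab7 (0.11) against PBS, pattern receptors in the combination minus PD-1Ab7 (0.18) and lung epithelial markers in the combination minus PBS (0.13), and ended the call of T cell markers in PD-1Ab minus PBS (-0.33). With protein-coding models alone that T cell call also ended (-0.27), and pattern receptors in the combination minus PD-1Ab7 were called (0.17). Without markers of other cell types the chemokine list in PD-1Ab7 minus PD-1Ab reversed to -0.042, the call of chemokine receptors in PD-1Ab minus PBS ended (-0.32), and pattern receptors in the combination minus PD-1Ab7 were called (0.17).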

Other observations

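The tests in this part were all chosen after the results were seen, and each pattern rests on single libraries. Intervals of the differences between list medians came from resampling list members. Members are expressed together, so these intervals understate the spread, and they leave out variation between libraries. The treatment named by the design stays open as an explanation of each and was not tested.

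Alveolar macrophage transcripts were lower in the PD-1Ab library than in the PBS library. Scaling of the library does not account for it, since the median over all genes was -0.05, and a higher share of cDC1 RNA as the whole cause would lower all other cell types alike, whereas endothelial and alveolar macrophage list medians stood 3.02 apart (2.43 to 3.56). A lower share of macrophage RNA and a lower level of these genes in each cell cannot be told apart: 15 of 15 markers were lower (median -2.07), which both would give. The most abundant markers, Chil3, Ear2, Marco, Atp6v0d2 and Car4, stood at 861, 926, 109, 104 and 81.5 RPKM in the PBS library and at 141, 219.9, 34.9, 17.9 and 26.9 in the PD-1Ab library. The list shares 1 member with the cDC1 list, and the labels name a sort for cDC1, which should remove macrophages, but they give no gate.

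Mature migratory DC transcripts were lower in the combination library than in the PD-1Ab7 library. Scaling does not account for it, since the median of all genes was 0.05 against -0.75 for the list. The mature list stood at -0.50 relative to cDC1 identity genes (-0.66 to -0.23). Dilution of cDC1 RNA as the whole cause would lower both lists alike only if other cells made neither list's genes. That was not tested, so dilution stays open. A lower share of CCR7-high cells among the sorted cells and a lower level in each cell cannot be told apart: 18 of 18 members were lower, which both would give, and bulk libraries hold no values per cell. Of the list, 3 genes are also in the inhibitory list, 2 in the chemokine list, and 1 each in the chemokine receptor, interferon gamma, NF-kB and actin lists.

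T cell transcripts were higher in the combination library than in the PBS library. A lower share of cDC1 RNA as the whole cause would raise all other cell types alike, whereas T cell and B cell list medians stood 1.99 apart (1.61 to 2.27). A higher share of T cell RNA and a higher level of these genes in the sorted cells cannot be told apart: 18 of 18 markers were higher (median 1.08), which both would give. The most abundant markers, Thy1, Il7r, Trbc1, Cd8b1 and Cd3g, stood at 36.0, 20.4, 23.3, 19.8 and 23.1 RPKM in the combination library and at 11.1, 11.7, 11.7, 8.93 and 6.13 in the PBS library. No other list holds a member; a sort for cDC1 should remove T cells, but the labels give no gate and the title line of the table calls the cells cDC1 T cells, so Pdcd1 at 15.2 RPKM and Ctla4 at 99.9 RPKM in the combination library could come from T cells as well as from cDC1.

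Ighg3 stood at 34.5 RPKM in the PBS library and at 0.583, 0.697 and 0.860 RPKM in the PD-1Ab, PD-1Ab7 and combination libraries. Ighg1 stood at 0.685 RPKM in the combination library and at 9.60 to 11.9 RPKM in the others. Mcpt1 stood at 22.2 RPKM in the PD-1Ab7 library, 2.47 in the combination and 0.230 or below in the other libraries. Tcrg-C2 stood at 0.898, 1.04, 5.30 and 13.1 RPKM in the PBS, PD-1Ab, PD-1Ab7 and combination libraries.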
